A study of Nicotiana tabacum with 39 samples.

How the data were processed

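RNA was measured in leaves of Nicotiana tabacum, the allotetraploid cultivated tobacco, during de-etiolation, the greening of pale leaves that follows a return to light. Per the labels' protocols, plants were grown on soil to near maturity with 16 h of light per day at 350 uE/m2/s and were then kept in extended darkness, whose length is not given in the sources used here. The clock time of the control harvest is not given either. The middle sections of 2 young leaves from each of 3 plants were pooled into 1 biological repeat, so each library is a pool and the spread between libraries is the spread between pools. Libraries were made from polyA RNA with the TruSeq method and sequenced as single-end reads of 100 bp on a HiSeq2500, per the labels' protocols. The extraction text in the labels also describes plants and harvests of a different design, and nothing in that part was used.

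Each of the 39 deposited tables holds raw whole-number counts per transcript, with no normalization by the authors visible in the values. FastQC 0.10.1, BWA 0.70 and SAMtools 1.0 are named in the submitters' processing notes without their roles. The reference sequences, the counting tool, the treatment of reads that map to several sequences and the strand setting are not given in the sources used here. Tobacco carries near-identical gene copies from its parent species, so reads shared between copies could have been split or lost in ways that the counts do not show. Neighbours were taken in the deposited order after low counts had been removed as described below. Identifiers next to each other in that list had a median Pearson correlation of 0.38 across the 39 libraries, and 22.7% of such pairs were above 0.80. For identifiers 50 places apart in it the median was -0.0058. Counts of transcripts are therefore not counts of independent genes.

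Transcripts are identified in the tables by NCBI GI number only, and the reference table used for names holds no GI numbers. None of the 53725 identifiers (0 matches) could thus be paired with the 79372 genes of that table (assembly ASM71507v2). This follows from the type of identifier and does not mean that the transcripts cannot be named from another source. The lists of photosynthesis, chlorophyll, carotenoid, clock, stress, cell wall and tissue marker genes fixed beforehand were for that reason not tested, and neither was the planned competitive test of those lists with camera. No chromosome position or gene name is given for any transcript. At most 2 transcripts that rose and 2 that fell are printed by identifier.

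Analyses were run in R 4.3.3. Low counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 42181 transcripts for testing and set aside 11544. The tested transcripts held 99.9% of all counts. Library sizes were scaled by the trimmed mean of M values (TMM). A negative binomial quasi-likelihood model with 1 mean for each of the 13 groups was fitted to all 39 libraries together (glmQLFit), so that every comparison shared 1 estimate of the spread, and 14 contrasts were tested with glmQLFTest. Adjusted p-values are Benjamini-Hochberg values over the tested transcripts within a contrast. The SE printed with a log2 difference is its absolute value divided by the square root of the F statistic. It thus restates the test and is not a separate estimate of spread. A transcript is said to have changed, risen or fallen where its adjusted p was below 0.05, and the number that also differed at least 2-fold is given beside the total. An F test of the 11 light times against the end of darkness together gave the transcripts that changed at any time. The median biological coefficient of variation was 19.2%.

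To follow groups of transcripts without counting the values that selected them, each group was chosen with the libraries of 2 replicate numbers at an adjusted p below 0.05 and at least 2-fold, and its median log2 CPM was measured in the remaining replicate number. This was done for each of the 3 replicate numbers in turn. Such held-out medians are given as the mean ± SD of 3 rotations. CPM were computed from the deposited counts with TMM scaling, and a prior count of 1 was added before taking logarithms. The share of a dark change that had been undone is 100% at the control level and 0% at the level at the end of darkness. Dark change stands here for the difference between the end of darkness and control, whatever its cause.

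The naming rule, fixed before the data were examined, took for each contrast the 10 largest rises and the 10 largest falls among changed transcripts with a mean of at least 10 CPM in the higher group and no overlap between replicates. The falling transcripts named are the 2 largest falls at 30 min under that rule. The rising transcripts named are the 2 that changed at 10 min. Neither meets the rule at 10 min. For 698441986 the replicates overlapped, with 2.38 CPM at 10 min and 2.39 CPM at the end of darkness. For 698576335 they did not overlap, but its mean at 10 min was 9.20 CPM, below the minimum of 10 CPM. Both were chosen after their values were seen.

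Library totals ran from 15844109 to 37269515 counts with a median of 21130744. No pair of libraries within a group was close to sampling noise, since the chi-square per degree of freedom between replicates ran from 3.73 to 47.2. Pearson correlations of log2 CPM between replicates across transcripts ran from 0.949 to 0.987. The procedure was tested on simulated counts drawn with the mean levels at the end of darkness, for all groups, and the library sizes of the real libraries. Of 42181 transcripts 200 were changed, all with an expected count of at least 10 at the median library size. Offsets between replicate numbers were not simulated. For 5 min against the end of darkness it recovered 8.96% of 1.5-fold, 47.8% of 2-fold and 89.4% of 4-fold changes, with 3 false calls among 100. For 10 min against the end of darkness the shares were 5.97%, 40.3% and 95.5%, with 5 false calls among 99.

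The replicate numbers come from the sample titles. Deviations of same-numbered libraries from their group means correlated above 0.10 for every replicate number in 4 contrasts, those of 5 min, 10 min, 2 h and 16 h with the end of darkness. In these contrasts the numbers pair the libraries. Over the 14 contrasts the correlations ran from -0.17 to 0.60. Alternatives fixed before the data were examined were a replicate block, size factors by the RLE method of DESeq2, scaling by library size only, no filter, a filter of at least 1 CPM in at least 6 libraries, DESeq2 1.42.0 in place of edgeR, a fit of the 6 compared libraries alone, each replicate number left out of all groups and each library of a contrast left out. Alternatives and comparisons chosen after seeing the data were thinning of all libraries to the smallest total, the steps between neighbouring times, each light time against control, and other scalings of the held-out libraries. Random regroupings of the whole time course were refitted with limma 3.58.1.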

Results

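The study followed the transcriptome of young tobacco leaves that were kept in extended darkness and then returned to light. In de-etiolation, etioplasts, the plastids of dark-grown tissue, become chloroplasts. Neither plastid state nor paleness is measured by the counts used here. There were 13 groups of 3 libraries each. A control group had received no dark treatment, and 1 group was harvested at the end of darkness (0 min). The other 11 groups were harvested 5, 10 and 30 min and 1, 2, 4, 8, 16, 40, 64 and 112 h after the return to light. Time in light stands here for the time since that return, and nights within the later times are not accounted for. The last 4 times lie whole days apart and thus share a clock time. No light time lies whole days after 0 min, so each comparison with 0 min is also one of different clock times. No plants kept in darkness were sampled at the light times. Library totals ran from 15844109 to 37269515 counts. Control libraries held 22799716, 22967639 and 34679672 counts, and those at the end of darkness 17762323, 18709986 and 19723283.

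Over the whole course, 35372 of the 42181 transcripts tested (83.9%) changed at some time after the return to light (edgeR quasi-likelihood F test over 11 light times, adjusted p below 0.05). The libraries lined up by time in light. On the first principal component, with 40.6% of the variance, libraries from 0 to 30 min scored from 90.2 to 140.0 and control libraries from -74.2 to -59.1. Libraries at 2 h lay between, from -20.9 to 20.2, and from 4 h onward none scored above -32.0. The second component (16.9%) placed 8 h at one end, with scores from -106.8 to -62.7, and 112 h at the other, with scores from 96.8 to 138.4.

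**Figure D1:**
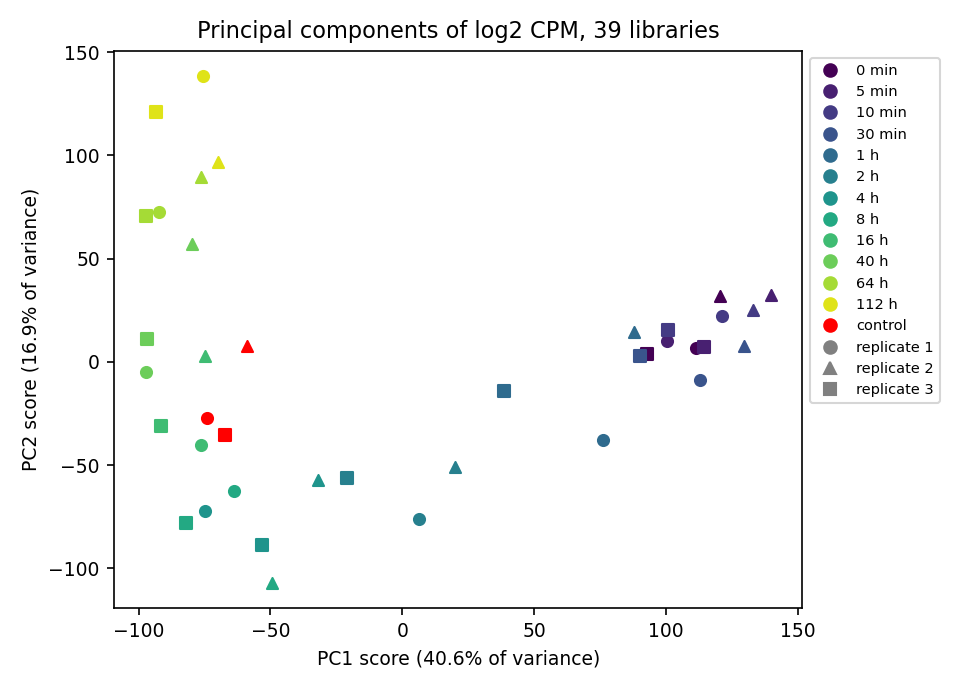
Scores of the 39 libraries on the first (40.6% of variance) and second (16.9%) principal components of log2 CPM, coloured by time in light with control in red, and with 1 symbol per replicate number. Libraries from 0 to 30 min sit at 90.2 or above on the first axis, control and all libraries from 4 h onward at -32.0 or below, and the libraries at 112 h lie highest on the second axis, at 96.8 or above.

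The first comparison sets leaves at the end of darkness against control. Because the clock time of the control harvest is not given, a part for time of day in these differences cannot be split off. At the end of darkness 20927 transcripts differed from control, with 10805 higher and 10122 lower, which is 49.6% of those tested. At least 2-fold differences numbered 5208 up and 4821 down, and at least 8-fold differences 341 up and 251 down. The median change was 0.98 on the log2 scale among transcripts that rose and -0.97 among those that fell. Transcripts that rose made up 35.0% of all counts at the end of darkness against 13.8% in control. Chosen without the libraries in which they were measured, the transcripts raised at least 2-fold in darkness (4562 to 4966 of them) lay 1.37 ± 0.07 above control, and those lowered (4234 to 5130) stood at -1.30 ± 0.06 relative to it (held-out medians, log2, SD, n = 3). The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scaling by library size only gave 14367 higher and 6644 lower, a share of 68.4% higher in place of 51.6%, so the balance of rises and falls rests on the scaling.

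Transcripts 698498471 and 698449936 were strongly raised in darkness and later showed the largest falls at 30 min. Transcript 698498471 stood at 18.6 ± 6.77 CPM in control and 340.2 ± 99.7 CPM at the end of darkness (SD, n = 3), a log2 difference of 4.19 (SE 0.52, adjusted p = 9.13e-08, edgeR). For 698449936 the levels were 0.405 ± 0.076 and 57.2 ± 19.2 CPM, a 141-fold rise (log2 7.14, SE 0.46, adjusted p = 1.37e-13, edgeR). All 3 dark libraries were above all 3 control libraries for both.

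Harvests at 5 and 10 min ask how soon light altered the transcriptome. At 5 min no transcript differed from the end of darkness by edgeR (0 changed) or by DESeq2 (0 changed), with 415 at an unadjusted p below 0.05. At 10 min 2 transcripts had changed and both were higher, with 604 at an unadjusted p below 0.05. The 415 and 604 are fewer than a share of 0.05 of the 42181 tested, which unchanged transcripts would give, so these tests were conservative. The model had no term for replicate number, although same-numbered libraries were correlated. The correlations with 0 min were 0.30, 0.60 and 0.38 at 5 min and 0.29, 0.49 and 0.47 at 10 min. Few calls are thus no evidence of an unchanged transcriptome. Transcript 698441986 rose from 1.91 ± 0.57 CPM to 56.9 ± 75.9 CPM (log2 4.91, SE 0.84, adjusted p = 0.0341, edgeR, n = 3), and 698576335 from 1.21 ± 0.34 to 9.20 ± 9.52 CPM (log2 2.95, SE 0.50, adjusted p = 0.0341, edgeR). The replicates at 10 min were far apart. For 698441986 they stood at 24.7, 2.38 and 143.5 CPM, and for 698576335 at 5.44, 2.14 and 20.02 CPM. Replicate 3 thus carried most of each rise in mean CPM. At 5 min neither was called, with log2 1.19 (SE 0.82) and 0.82 (SE 0.53). Replicates 1 to 3 then stood at 3.16, 1.12 and 8.62 CPM for 698441986 and 1.65, 2.42 and 2.36 CPM for 698576335. Those of 698576335 were all above the 3 libraries at the end of darkness (1.14, 1.58 and 0.92 CPM), and those of 698441986 were not.

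Without replicate 3 at 10 min the rises of 698441986 and 698576335 fell to log2 2.86 (SE 0.68) and 1.69 (SE 0.40), and no transcript was called (0 changed, edgeR). Leaving out any 1 library of the end of darkness also ended both calls (0 changed in each case), but with little change in fold. Log2 values then ran from 4.69 to 5.10 and from 2.78 to 3.17, and SE rose from 0.84 to between 0.99 and 1.02 and from 0.50 to between 0.58 and 0.60. The 6 libraries fitted alone gave log2 4.91 (SE 1.25) and 2.95 (SE 0.76), again with 0 changed. Without replicate 1 at 10 min 7 transcripts changed, without replicate 2 at 10 min 25, and DESeq2 called 7.

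By 30 min 2484 transcripts had changed, with 1166 higher and 1318 lower, and 602 and 327 of these by at least 2-fold. Rises were larger than falls, with medians of 1.04 and -0.71 among changed transcripts and 59 rises but 10 falls of at least 8-fold. Transcripts lowered at least 2-fold at 30 min (210 to 324) were ones that stood 1.5 ± 0.30 above control at the end of darkness. They came down to 0.36 ± 0.11 at 30 min and 0.028 ± 0.037 at 1 h, or 0.61 and 0.19 with scaling by library size only. Transcripts raised at 30 min (257 to 493) passed the control level, from -0.46 ± 0.21 at the end of darkness to 1.03 ± 0.43 at 30 min (held-out medians relative to control, log2, SD, n = 3), or from -0.24 to 1.28 with library size only. At 112 h their position relative to control was 0.16 ± 0.45, with 0.61, 0.16 and -0.29 in the 3 rotations. Relative to the end of darkness these transcripts were up by 1.40 ± 0.44 at 30 min and 0.73 ± 0.02 at 2 h, and stood at 0.15 ± 0.13 at 8 h, 0.37 ± 0.15 at 64 h and 0.62 ± 0.26 at 112 h. These last values were 0.091, 0.16 and 0.41 with library size only. Scaling by library size only gave 1130 higher and 904 lower at 30 min, a share of 55.6% higher in place of 46.9%, so the more frequent direction turned.

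The named transcripts moved at 30 min in all 3 libraries. Transcript 698441986 stood at 36.8 ± 9.96 CPM (log2 4.28 against the end of darkness, SE 0.82, adjusted p = 0.000805, edgeR) and stood at 3.27 ± 0.40 CPM at 2 h against 3.23 ± 0.42 CPM in control. Transcript 698576335 reached 10.3 ± 2.40 CPM (log2 3.09, SE 0.50, adjusted p = 8.61e-05, edgeR). Transcript 698498471 fell to 18.4 ± 3.56 CPM (log2 -4.21, SE 0.52, adjusted p = 1.98e-06, edgeR), and to 2.46 ± 0.77 CPM at 2 h. Transcript 698449936 fell to 3.12 ± 0.26 CPM (log2 -4.20, SE 0.37, adjusted p = 8.00e-09, edgeR) and to 0.355 ± 0.196 CPM at 2 h. The rise of 698441986 lost significance without replicate 1 of all groups (log2 4.47, adjusted p = 0.0614, edgeR). The 6 libraries of 0 and 30 min fitted alone gave 1133 changed transcripts, and leaving a whole replicate number out of all groups gave 1062, 1365 and 865.

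At 112 h both risers were again above the end of darkness, 698441986 at 7.46 ± 6.34 CPM (log2 1.98, SE 0.81, adjusted p = 0.0423, edgeR) and 698576335 at 2.92 ± 2.01 CPM (log2 1.28, SE 0.52, adjusted p = 0.0405, edgeR). Without replicate 2 at 112 h the log2 values were 1.04 (SE 0.87) and 0.54 (SE 0.55) and both calls were lost (adjusted p = 0.341 and 0.447, edgeR). Leaving replicate 2 out of all groups gave 1.24 (SE 0.80) and 0.77 (SE 0.55), leaving out replicate 1 gave 2.18 (SE 1.19) and 1.47 (SE 0.70), and both calls were lost in each case. The calls were also lost with scaling by library size only, where the log2 values were 1.80 (SE 0.82) and 1.09 (SE 0.53), with adjusted p = 0.0660 and 0.0839 (edgeR). Without replicate 1 of the end of darkness they were 2.04 (SE 0.96) and 1.24 (SE 0.60), adjusted p = 0.0851 and 0.0949 (edgeR), and without its replicate 3 1.75 (SE 0.93) and 1.11 (SE 0.59), adjusted p = 0.128 and 0.130 (edgeR). For 698441986 the call also ended with a higher fold, at 2.16 (SE 0.96, adjusted p = 0.0646, edgeR) without replicate 2 of the end of darkness and 2.11 (SE 0.87, adjusted p = 0.0503, edgeR) without replicate 1 at 112 h.

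**Figure D2:**
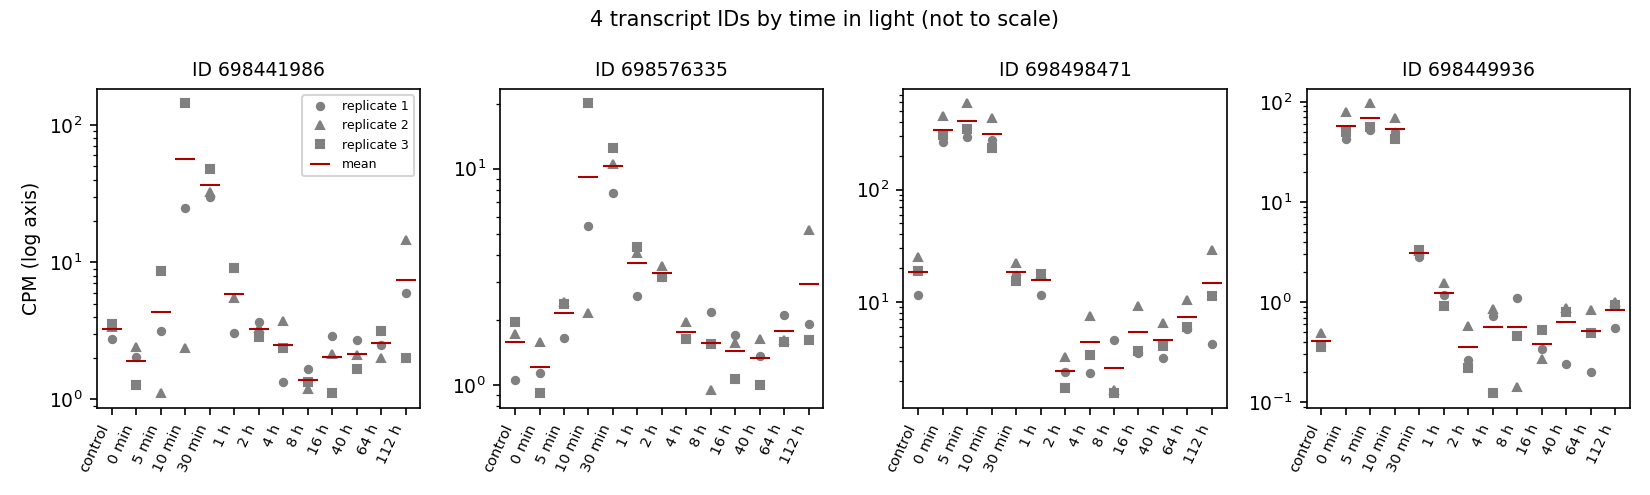
CPM on a log axis of 4 transcripts in control and at each time in light (times not to scale), with 1 grey symbol per replicate and a red dash for the mean of 3. Identifiers 698441986 and 698576335 stood at 36.8 and 10.3 CPM at 30 min with scattered replicates at 10 min, while 698498471 and 698449936 fell from 340.2 and 57.2 CPM at the end of darkness to 18.4 and 3.12 CPM at 30 min.

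Between 30 min and 2 h the change spread through the transcriptome. At 1 h 10788 transcripts differed from the end of darkness (5472 higher and 5316 lower, 2131 and 1690 by at least 2-fold), and at 2 h 17034 did (8293 and 8741, with 3576 and 3590 by at least 2-fold). Transcripts raised at least 2-fold at 1 h (1664 to 2141) went from -0.79 ± 0.12 relative to control at the end of darkness to 0.59 ± 0.16 at 1 h and 0.71 ± 0.23 at 2 h, then stood at 0.061 ± 0.081 at 4 h, which was 0.23 with library size only (held-out medians, log2, SD, n = 3). Transcripts lowered at 1 h (1150 to 1794) had stood 1.28 ± 0.08 above control and reached 0.069 ± 0.136 by 1 h, or 0.23 with library size only. Scaling by library size only gave 4402 higher and 5423 lower at 1 h (44.8% higher in place of 50.7%), and 6795 and 9560 at 2 h (41.5% in place of 48.7%). Fitting the 6 libraries of 0 min and 1 h alone gave 5316 changed transcripts at 1 h. Leaving out replicate 1 or replicate 3 of all groups gave 5318 and 6404 at 1 h, and 11183 and 11097 at 2 h.

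**Figure D3:**
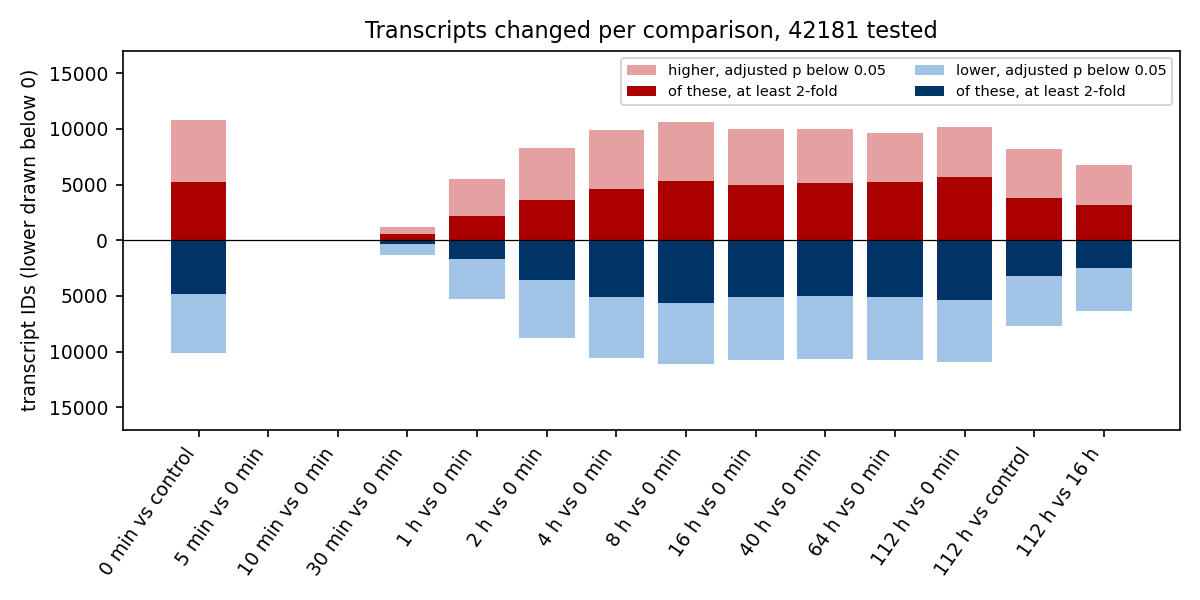
Transcripts higher (red, above 0) or lower (blue, below 0) in each of 14 comparisons, pale for adjusted p below 0.05 and dark for those that also differed at least 2-fold, of 42181 tested. The total went from 0 at 5 min and 2 at 10 min to 2484 at 30 min, 10788 at 1 h and 21737 at 8 h, and the balance of higher and lower depends on the scaling, since library size only gave 55.6% higher in place of 46.9% at 30 min, 41.0% in place of 48.3% at 16 h and 68.4% in place of 51.6% for 0 min vs control.

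Between 4 and 16 h most of the dark change had gone. The transcripts that differed from the end of darkness numbered 20422 at 4 h (9882 higher, 10540 lower), 21737 at 8 h (10645 and 11092) and 20705 at 16 h (9998 and 10707). At least 2-fold differences were 4597 up and 5125 down at 4 h, 5329 and 5660 at 8 h, and 4992 and 5093 at 16 h. For transcripts raised in darkness, 8.40 ± 4.87% of the change was undone at 30 min, 36.5 ± 7.34% at 1 h, 69.7 ± 8.19% at 2 h, 89.4 ± 1.32% at 4 h and 93.6 ± 3.65% at 16 h (SD, n = 3). For those lowered in darkness the shares were 7.62 ± 9.27% at 30 min, 30.8 ± 6.61% at 1 h, 59.7 ± 12.1% at 2 h, 81.4 ± 10.7% at 4 h and 98.9 ± 4.72% at 16 h. With scaling by library size only the shares were 34.9 ± 5.00% and 32.0 ± 9.19% at 1 h, 80.3 ± 3.71% and 93.1 ± 10.2% at 4 h, and 85.9 ± 6.92% and 111.1 ± 3.10% at 16 h for the raised and lowered groups, so which group returned faster depends on the scaling. At 16 h the raised group lay 0.089 ± 0.051 above control (0.22 with library size only). The lowered group stood at -0.012 ± 0.059, which became 0.12, so no side of control can be given for it. With library size only the share of higher transcripts against the end of darkness was 43.8% in place of 48.4% at 4 h, 44.6% in place of 49.0% at 8 h and 41.0% in place of 48.3% at 16 h.

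**Figure D4:**
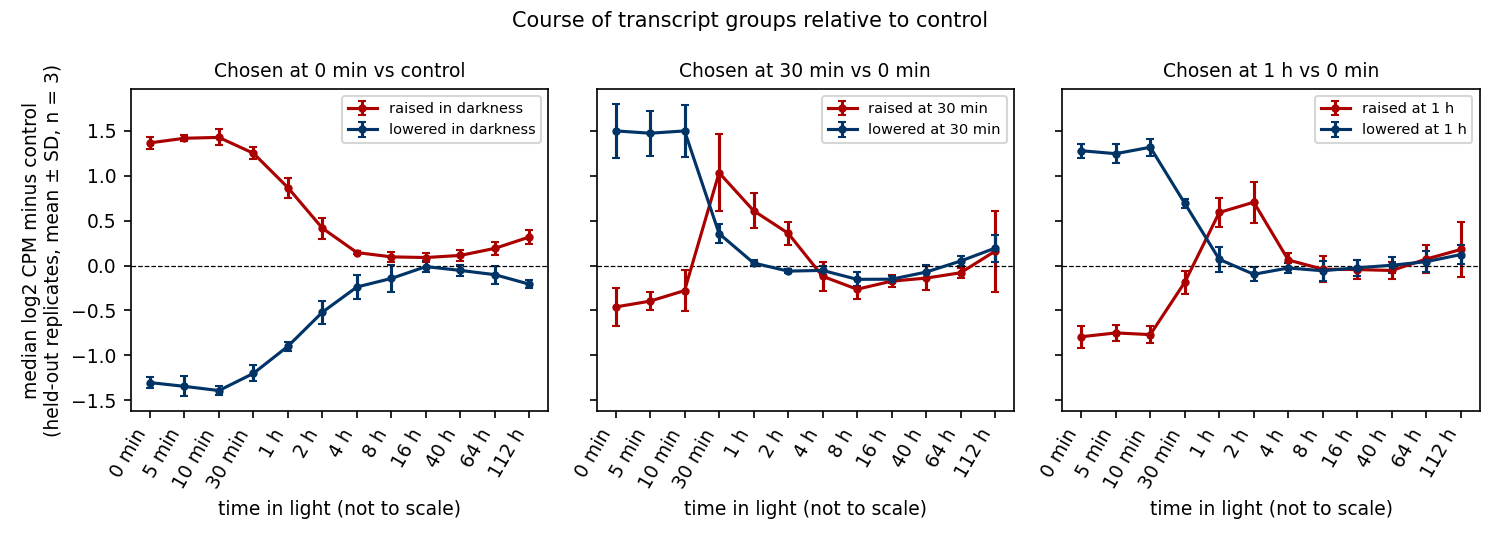
Held-out median log2 CPM minus control (mean ± SD, n = 3) against time in light, not to scale, for transcripts chosen at 0 min against control (left), at 30 min (middle) and at 1 h (right) against 0 min, with raised groups in red and lowered groups in blue. The dark-raised group went from 1.37 at 0 min to 0.42 at 2 h and 0.089 at 16 h, and the group raised at 30 min reached 1.03 at 30 min.

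From 40 to 112 h the number of transcripts that differed from the end of darkness stayed near its level at 16 h, with 20630 at 40 h (9946 higher, 10684 lower), 20370 at 64 h (9617 and 10753) and 21022 at 112 h (10140 and 10882). Differences of at least 2-fold were 5134 up and 5016 down at 40 h, 5204 and 5054 at 64 h, and 5711 and 5355 at 112 h. Large rises became more frequent, with 224 of at least 8-fold at 16 h, 304 at 40 h, 479 at 64 h and 698 at 112 h. Large falls did not, at 393, 395, 363 and 373. Transcripts higher at 112 h than at the end of darkness held 54.5% of the counts at 112 h and 23.0% before the return to light. Scaling by library size only moved the balance, to 7425 higher and 12864 lower at 40 h (36.6% higher in place of 48.2%), 6650 and 14200 at 64 h (31.9% in place of 47.2%), and 7207 and 14395 at 112 h (33.4% in place of 48.2%).

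Of the 21208 transcripts that differed at least 2-fold from the end of darkness at any light time, 4.38% had done so first by 30 min, 19.5% by 1 h, 39.7% by 2 h, 61.0% by 4 h and 80.4% by 16 h. The remaining share was reached by 40 h (86.7%), 64 h (93.6%) or 112 h. First differences at 112 h numbered 677 up and 678 down.

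The comparison of 112 h with control asks whether leaves ended where untreated leaves stood. They did not in transcript levels, since 15873 transcripts differed (8144 higher, 7729 lower), of which 3812 and 3211 by at least 2-fold. Median changes were 0.95 among those higher and -0.87 among those lower. Dark-raised transcripts stood 0.32 ± 0.08 above control and dark-lowered ones at -0.21 ± 0.05 (held-out medians, log2, SD, n = 3). The shares undone were 76.9 ± 4.45% and 83.9 ± 4.34%. In both groups the highest of 3 values at 112 h (81.7% and 87.2%) was under the lowest at 16 h (90.3% and 93.6%). With scaling by library size only this held for the dark-lowered group (86.1% against 109.2%) but not for the dark-raised group (91.7% against 78.6%). In 1 rotation both times share transcripts, control and dark libraries, so the values are 3 pairs, too few for a test. The ranges do not use this pairing. From 16 h to 112 h the dark-raised group went from 0.10 to 0.39, 0.13 to 0.33 and 0.033 to 0.24 relative to control (log2). The dark-lowered group went from 0.037 to -0.19, -0.078 to -0.26 and 0.0052 to -0.17. Without replicate 1 or replicate 3 of all groups 8288 and 9201 transcripts differed.

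The comparison of 112 h with 16 h sets 2 harvests at the same clock time against each other. Between them 13131 transcripts differed, with 6786 higher and 6345 lower at 112 h, and 3118 and 2531 by at least 2-fold. Transcripts raised at least 2-fold over this interval (1376 to 3671) went from -0.14 ± 0.06 relative to control at 16 h to 0.25 ± 0.11 at 40 h, 0.86 ± 0.23 at 64 h and 1.34 ± 0.59 at 112 h. With library size only the value at 16 h was -0.0070, so no side of control can be given for it. Those lowered (1377 to 3532) went from 0.18 ± 0.16 at 16 h (0.31 with library size only) to -0.19 ± 0.24 at 40 h, -0.91 ± 0.20 at 64 h and -1.52 ± 0.70 at 112 h (held-out medians, log2, SD, n = 3). Scaling by library size only gave 4670 higher and 7970 lower, or 36.9% higher in place of 51.7%. Without replicate 1 or replicate 3 of all groups 4576 and 6572 transcripts differed.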

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

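The test on the 64 h libraries and the comparison of 112 h with 1 h were chosen after the results were seen, and the other tests in this part were planned or stated before their outcome.

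A difference between times brought up the 13131 transcripts whose change from the end of darkness was not the same at 16 h and 112 h, tested as the direct contrast of both times. Unequal depth and scaling are argued against as the whole cause, since 12166 transcripts still differed with all libraries thinned to equal depth and 12640 with scaling by library size only. The lowest count with 1 library left out was 8786, without replicate 1 at 112 h, and leaving replicate 1 out of every group gave 4576. A disturbance of the 112 h harvest alone is argued against by the transcripts raised from 16 h to 112 h, which already stood 1.01 ± 0.29 above their 16 h level at 64 h (held-out medians, log2, SD of 3 rotations, n = 3). Leaf age, days since the return to light and a lasting effect of darkness may each contribute and stay open. No untreated leaves of matching age were analysed here.

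Transcripts that differed at least 2-fold from the end of darkness in opposite directions at 1 h and 112 h numbered 105, with 62 up at 1 h and down at 112 h and 43 the other way. The choice of these transcripts all but fixes a difference between 112 h and 1 h, so that contrast adds no support. Independent lists of the same sizes would share 271 and 229. In the same direction 992 were up at both times and 965 down at both. In 5 simulations of groups with no change against the same dark libraries 0 transcripts were called, so these give no chance level for either overlap. Both comparisons use the same 3 dark libraries, which adds to the overlap in the same direction by an amount that could not be split off.

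Transcript 698498471, which had fallen at 30 min, was higher at 112 h than at 16 h by 1.44 on the log2 scale (SE 0.50, adjusted p = 0.0278, edgeR, means of 14.8 ± 12.6 and 5.44 ± 3.20 CPM, n = 3), and the replicates at 112 h stood at 4.22, 28.7 and 11.4 CPM. Without replicate 2 at 112 h the log2 value was 0.48 (SE 0.51, adjusted p = 0.514, edgeR). The call was also lost, with folds within 1 SE of the reported value, without replicate 1 at 16 h (log2 1.21, SE 0.57, adjusted p = 0.129), replicate 3 at 16 h (1.19, SE 0.58, 0.142) or replicate 3 of all groups (1.38, SE 0.72, 0.213), and with 6 libraries alone (1.40, SE 0.58, 0.0828, edgeR). Over all alternatives the adjusted p ran from 0.00306 to 0.514 (edgeR).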

How the results depend on the processing

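Equal-depth thinning was chosen after seeing the data. Of 119 counts of changed transcripts recomputed under alternatives other than leaving libraries out, 115 were within 1.5 times the reported count, among them all 15 under scaling by library size only, RLE size factors, no filter, the stricter filter and equal depth. The exceptions were 10 min against the end of darkness with DESeq2 (7) and with 6 libraries alone (0), and 30 min (1133) and 1 h (5316) with 6 libraries alone. Fewer libraries entered those last fits, and the cause for DESeq2 was not tested. Library size only moved the median of all transcripts by over 0.10 log2 in 5 contrasts, from 0.027 to 0.25 for 0 min against control, from 0.043 to -0.087 for 112 h against 16 h and, against 0 min, from -0.029 to -0.19 at 40 h, -0.048 to -0.27 at 64 h and -0.039 to -0.26 at 112 h. Which direction was the more frequent is not settled, since in all 12 contrasts with over 2 calls at least 1 of 8 alternatives turned it. The share of higher transcripts ran from 31.9% to 68.4%, and without library size only from 45.3% to 53.7%.

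With libraries or whole replicate numbers left out, counts ran from 15071 to 19458 for 0 min against control. Against 0 min they ran from 0 to 0 at 5 min, 0 to 25 at 10 min, 865 to 2481 at 30 min, 5318 to 12044 at 1 h, 11097 to 15980 at 2 h, 14144 to 19291 at 4 h, 16399 to 20346 at 8 h, 14589 to 19209 at 16 h, 14467 to 19320 at 40 h, 14919 to 18765 at 64 h and 15427 to 19984 at 112 h. They ran from 8288 to 15698 for 112 h against control, 4576 to 13859 for 112 h against 16 h and 27792 to 36503 for the whole course. Fewer libraries in the fit are part of the construction. Among 221 recomputed fold changes of the 4 named transcripts, 187 stayed on the same side of the threshold, 34 lost significance and 0 changed direction. No loss fell on 698449936.

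The replicate block moved none of the 15 planned counts by over 1.5 times and ended none of the calls named in the report. It gave 0 at 5 min, 3 at 10 min, 18776 at 2 h and 22285 at 16 h, where the numbers pair the libraries. In the 10 contrasts where at least 1 replicate number did not correlate above 0.10 it gave, for example, 3532 at 30 min and 12844 at 1 h. It gave 17701 for 112 h against control and 15075 for 112 h against 16 h. Some of the 10 were paired in part, with correlations of 0.035, 0.35 and 0.41 at 30 min and 0.095, 0.50 and 0.46 at 1 h. In 1 of the 10, 1 h against 0 min, all 6 libraries correlated best with their own number. Camera alternatives were not run because no list could be tested. With the depth and spread of the real libraries, 47.8% of simulated 2-fold changes were recovered at 5 min and 40.3% at 10 min, and the parts of depth and spread in this were not separated.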

Other observations

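The steps between neighbouring times, the comparisons of each light time with control and the tests at 5 and 10 min on held-out medians and on left-out libraries were chosen after the data were seen.

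The steps between neighbouring times gave unequal counts. Transcripts that changed numbered 2592 from 10 to 30 min, 4051 from 30 min to 1 h, 6631 from 1 to 2 h and 6932 from 2 to 4 h. From 4 to 8 h none was called by edgeR (0, with 1174 at an unadjusted p below 0.05, and 1 by DESeq2). The 1174 are fewer than a share of 0.05 of the 42181 tested, so the test from 4 to 8 h was conservative too. From 8 to 16 h 4234 changed, with 1684 up and 2550 down. The day steps gave 11 transcripts from 16 to 40 h, 18 from 40 to 64 h and 288 from 64 to 112 h, with 2683, 4619 and 4695 at an unadjusted p below 0.05. These counts do not measure the size of the change, since 13131 transcripts differed between 16 h and 112 h. Single libraries moved these counts. Leaving out replicate 1 or 3 at 10 min gave 1631 and 1649 for 10 to 30 min, and replicate 1 or 2 at 30 min 1665 and 1713. Without replicate 2 at 30 min 2558 changed from 30 min to 1 h. For 1 to 2 h the count was 3226 without replicate 2 at 1 h, 4152 without replicate 1 at 2 h and 3771 without replicate 3 at 2 h. For 2 to 4 h it was 3852 without replicate 2 at 2 h and 2792 without replicate 1 at 4 h. For 4 to 8 h it was 77 without replicate 1 at 4 h and 45 without replicate 2 at 8 h. For 8 to 16 h it was 1981 without replicate 2 at 8 h, 1506 without replicate 2 at 16 h and 2691 without replicate 3 at 16 h. Leaving a whole replicate number out of all groups, with fewer libraries in the fit, lowered the counts further. The lowest were 806 for 10 to 30 min, 1281 for 30 min to 1 h, 1999 for 1 to 2 h, 1176 for 2 to 4 h and 828 for 8 to 16 h.

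The counts of the day steps rest on single libraries and settings. From 16 to 40 h the count was 25 without replicate 1 at 40 h, between 1 and 5 without any other of the 6 libraries, and 34 by DESeq2. From 40 to 64 h it was 1322 without replicate 2 at 40 h, 5 without replicate 3 at 64 h, 0 without any other of the 6 libraries or with library size only, 971 with the replicate block, 329 by DESeq2 and 9 at equal depth. From 64 to 112 h, leaving out replicate 1, 2 or 3 at 64 h gave 31, 148 and 19, and leaving out replicate 1 or 2 at 112 h gave 7 and 953. The block gave 758 there, DESeq2 616 and library size only 155.

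With TMM scaling the libraries at 16 h were the nearest to control. The number of transcripts that differed from control went from 20927 at 0 min to 22437 at 10 min, then 18755 at 1 h, 11871 at 2 h, 7258 at 4 h, 9104 at 8 h and 2708 at 16 h, and was 4087 at 40 h, 10187 at 64 h and 15873 at 112 h. The median absolute log2 difference was 0.58 at 0 min, 0.24 at 16 h, 0.26 at 40 h and 0.44 at 112 h. With library size only, the dark-raised and dark-lowered groups lay nearer to control at 40 h (held-out medians of 0.18 and 0.016) than at 16 h (0.22 and 0.12). For these groups the nearest time thus depends on the scaling. At 16 h the count was 1566, 1758 and 1612 without replicate 1, 2 or 3 at 16 h, and 1701 without replicate 2 of control. At 2 h it was 7723 without replicate 2 at 2 h, and at 4 h 4787 without replicate 2 of control. At 40 h it was 2516 without replicate 3 of control and 2278 or 2465 without replicate 2 or 3 at 40 h. At 64 h it was 6593 without replicate 2 at 64 h. With a whole replicate number left out of all groups the lowest counts were 4871 at 2 h, 2619 at 4 h, 5005 at 8 h, 732 at 16 h, 1061 at 40 h and 3331 at 64 h.

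Counts also became more concentrated late in the course. The 100 most abundant transcripts of a library held 19.3 ± 2.65% of its counts in control, 15.2 ± 2.77% at 0 min, 13.8 ± 1.01% at 8 h, 17.8 ± 1.81% at 16 h, 20.3 ± 1.91% at 40 h, 23.8 ± 1.06% at 64 h and 24.0 ± 2.35% at 112 h (SD, n = 3). The 13 groups differed by a permutation test of 100000 relabellings (p = 4e-05), and by 1 that relabelled within replicate numbers (p = 1e-05, the smallest it can give). Single pairs could not reach significance, since an exact two-sided permutation test of 3 against 3 goes no lower than 0.10 (0 min against control p = 0.20, 112 h against 0 min p = 0.10).

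The near absence of changed transcripts at 5 and 10 min is a pattern to weigh. The held-out median of the transcripts raised at 30 min stood 0.062 ± 0.10 above the end of darkness at 5 min (-0.019, 0.031 and 0.17 in the 3 rotations). This argues against a rise of the group median to 25% of the 30 min value (0.35 of 1.40 ± 0.44). A smaller rise, and rises of single transcripts by 5 min, stay open. At 10 min the value was 0.099 ± 0.228, with -0.023, -0.041 and 0.36 in the 3 rotations, so whether the rise may have begun by 10 min cannot be told apart from spread between pools. Offsets between replicate numbers that are shared by all times are argued against, since the replicate block gave 3 changed transcripts at 10 min. Lower depth is argued against, since thinning to equal depth left 2290 at 30 min. Offsets shared only by the early libraries stay open. The block fits 1 offset per replicate number to all 13 groups, and no paired fit of the early libraries was run. Same-numbered libraries correlated with those at 0 min at 0.30, 0.60 and 0.38 at 5 min, but at 0.025, 0.018 and 0.065 at 112 h. A response at 10 min that differed between replicates stays open, since 25 transcripts changed without replicate 2 at 10 min, and so does a change too small for the depth and spread of these libraries.

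The distance between 112 h and control is another such pattern. Unequal depth and scaling are argued against as the whole cause by 14478 changed transcripts at equal depth and 14903 with library size only. With 1 library left out the lowest count was 11874, without replicate 1 at 112 h. A difference in harvest clock time from control is argued against as the whole cause by 16 h, at the clock time of 112 h, where 2708 transcripts differed from control (732 to 3916 over all alternatives) against 15873. A part for clock time stays open, and leaf age and a lasting effect of darkness may each contribute and were not tested because the design ties them to the groups.

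Other splits of the 6 libraries of each contrast were compared by refitting those libraries alone. With 3 against 3 there are 10 splits, too few for a share under 0.05. In 12 contrasts the real split was the 1 split that gave calls, with the highest of the others at 0. Real counts were 18014 for 0 min against control and, against 0 min, 1133 at 30 min, 5316 at 1 h, 15393 at 2 h, 17457 at 4 h, 18060 at 8 h, 20334 at 16 h, 18643 at 40 h, 20576 at 64 h and 18952 at 112 h. They were 13231 for 112 h against control and 13819 for 112 h against 16 h. At 5 and 10 min all 10 splits gave 0. For the whole course the real grouping gave 35337 transcripts (limma) and was the 1 of 100 splits to reach that number, with 1747 as the highest of the others. This argues against chance only at a share of 1 in 100, the lowest the test can give. The regroupings ignored replicate numbers.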
